A study of Mus musculus with 11 samples.

How the data were processed

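RNA was taken from BV2 mouse microglial cells transfected with control or Tet2 siRNA by lipofection. Per the labels' protocols, LPS at 1 µg/ml followed 48 h after transfection, for 3 h, in medium with 5% serum, after growth in 10% serum. RNA was extracted with TRIzol, polyadenylated RNA was selected on beads and strand-specific libraries were made, per the labels. Per the submitters' processing notes, Trim Galore 0.3.3, TopHat2 2.0.9, the mm9 genome build and DESeq2 were used. The DESeq2 version, the read counter, the gene annotation and whether the counting used strand are not given in the sources used here. Genes with near-identical copies, such as members of the Ifit, Oas, Gbp and histone families, and overlapping or antisense genes are therefore uncertain.

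The single deposited table holds 26061 genes in 11 columns, 1 per library, of variance-stabilised values on a log2 scale, per the file headers and the values themselves. The lowest value, 4.02, is shared by all libraries and stands for 0 reads. Undoing the transform gave whole reads for 100% of values within 0.01 of a read, which gave the reads per library, from 8739716 to 23030426, and the normalised reads printed. For genes with few reads the log2 scale understates changes. No gene coordinates are printed, because the table gives none and the reference in hand is of another build, GRCm38. That reference was used for transcript length, GC content and names only, and 95.4% of symbols matched it, 22791 directly and 2068 through a synonym. A spreadsheet had turned 25 gene names into dates, and those genes are not named.

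Differential expression was computed with limma 3.58.1 in R 4.3.3 on the deposited values as they stand. One model with a mean per group was fitted to all 11 libraries, with moderated two-sided tests, a trend of the variance with expression and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. Genes were kept when at least 2 libraries lay at least 1 log2 unit above the lowest value, which left 12486. The comparisons were LPS against untreated in each siRNA group, Tet2 siRNA against control siRNA in each treatment, and the difference between both LPS responses. Tet2 was also tested by exact permutation of libraries. The size of the LPS response was compared over genes called by a weighted average of both LPS effects, with weights of 5/9 and 4/9. These make the choice of genes independent of the difference tested only if all libraries vary alike. Counting floors of 3 counts cover counting error only.

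Before the data were examined, 21 gene lists, the tests, the alternatives and the genes to be named were fixed. Lists were tested with limma's camera against all other genes with a preset correlation of 0.01, beside an estimated correlation, and adjusted over lists within a comparison. Of the 21 lists 19 were tested. Mitochondrially encoded RNAs had 0 of 15 members kept, and 3 of 24 markers of other cell types were kept, too few to test. Values of those markers, and of some single genes, are not reported here. Named genes were 13 fixed ones (Tet1, Tet2, Tet3, Tnf, Il1b, Il6, Nos2, Ptgs2, Ccl2, Ccl5, Cxcl10, Ifnb1 and Arg1), the 8 called genes with the largest increase and the 8 with the largest decrease, up to 4 members of each list with the smallest p, and, where fewer than 8 genes were called, the 5 genes with the smallest p.

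The procedure was tested on simulated counts drawn from the libraries' own means and sizes. Changed genes, 66 or 67 per fold, were drawn from well-expressed ones. Each simulated gene had the median spread of genes at its level. Genes that spread more and libraries that stand apart were not simulated, so recovery in the data can be lower than the shares below. For Tet2 siRNA in untreated cells it recovered 17.9% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 100% of those changed 4-fold among 12747 genes, with 2.22% of calls false. For Tet2 siRNA after LPS it recovered 13.4%, 73.1% and 98.5% in the same order among 12741 genes, with 4.65% of calls false. For the difference between LPS responses it recovered 4.48%, 25.4% and 95.5% among 12779 genes, with 5.68% of calls false. In 10 simulations with no effect, 0 of 193 list tests were called, but simulated genes vary independently, so this does not check the preset correlation.

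The alternatives fixed beforehand were no filter and a stricter filter (10605 genes), quantile normalisation, centring each library on its median, no variance trend, fits of only the groups compared, the replicate number as a block, library weights, an estimated correlation, and leaving out each library in turn. Chosen after the data had been seen were voom on recovered reads, removal of trends with transcript length and GC content, leaving out a pair of control siRNA libraries or of Tet2 siRNA libraries, a second estimator of library weights, and the Tet2 siRNA effect pooled over treatments in 2 forms. The main tests used the deposited log2 values. Apart from voom, no model of counts was used, although the recovered reads were whole. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.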

Results

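Polyadenylated RNA was sequenced from BV2 cells, an immortalised mouse microglial line, transfected with a control siRNA of no target or with siRNA against Tet2. Tet2 is an enzyme that oxidises 5-methylcytosine in DNA. From 48 h after transfection, cells were left untreated or given 1 µg/ml lipopolysaccharide (LPS), a bacterial ligand of Toll-like receptor 4, for 3 h. There were 3 libraries of untreated control siRNA cells, 3 of LPS-treated control siRNA cells, 3 of untreated Tet2 siRNA cells and 2 of LPS-treated Tet2 siRNA cells. The 11 libraries held between 8739716 and 23030426 reads on genes, with a median of 18844761. The shallowest were replicate 2 of the untreated Tet2 siRNA cells, with 8739716 reads, and replicate 3 of the untreated control siRNA cells, with 8764031. The latter detected 16406 genes, against 12866 to 14180 in the other 10 libraries. It enters the differences that use untreated control siRNA cells and, through the spread shared by all groups, the p-values of every comparison. Without it, LPS in Tet2 siRNA cells called 1774 genes in place of 1487. Because the labels do not say whether replicates were separate cultures, the p-values of single genes below measure the spread between these libraries. Those of camera compare the genes of a list with all other genes. With the preset correlation they assume how genes vary together and do not take it from these libraries. Differences are on the log2 scale of the variance-stabilised values, which understates the change of genes with few reads.

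Tet2 itself rose with LPS and was lower on average in the Tet2 siRNA cells, with ranges that lay apart from the controls after LPS but not before. Normalised Tet2 reads were 1974, 2382 and 1814 in untreated control siRNA cells, with a mean of 2057 ± 293 (SD, n = 3). Untreated Tet2 siRNA cells had 1443, 1974 and 1650, with a mean of 1689 ± 267 (SD, n = 3), so that the ranges of both untreated groups overlapped. After LPS, Tet2 reads were 10331, 16672 and 14657 with control siRNA, a mean of 13887 ± 3240 (SD, n = 3), and 7912 and 9172 with Tet2 siRNA, a mean of 8542 ± 891 (SD, n = 2). The Tet2 siRNA cells thus held 82.1% of the control mean untreated and 61.5% after LPS. On the log2 scale the Tet2 difference was -0.28 (SE 0.20) untreated, which did not pass the test (limma, unadjusted p = 0.175). It was -0.67 (SE 0.22) after LPS, with an unadjusted limma p of 0.00906 and an adjusted p of 0.165 over all genes. Two-sided exact permutation tests of Tet2 gave p = 0.2 for both siRNA differences, where the smallest p these groups allow is 0.1. LPS raised Tet2 by 2.72 (SE 0.20, adjusted p = 5.07e-07) in control siRNA cells and by 2.32 (SE 0.22, adjusted p = 1.11e-05) in Tet2 siRNA cells. Exact permutation tests of Tet2 gave p = 0.1 for both LPS differences, the smallest possible. Among its relatives, Tet3 fell by 0.69 (SE 0.18, adjusted p = 0.0138) with LPS in control siRNA cells, while its LPS difference in Tet2 siRNA cells was -0.27 and did not pass (adjusted p = 0.541). The Tet3 call in control siRNA cells ended without replicate 2 of the LPS-treated ones (-0.61, adjusted p = 0.0612).

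**Figure D1:**
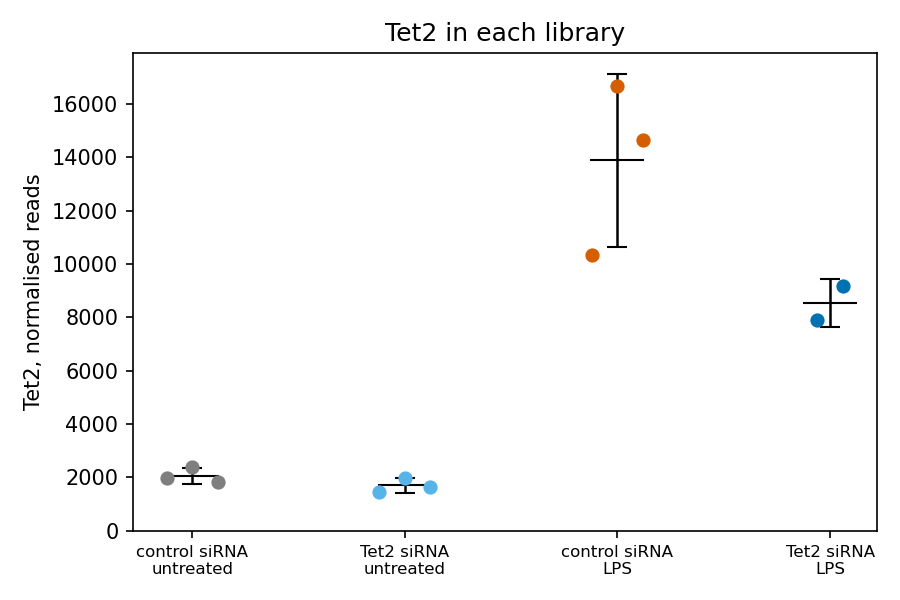
Normalised Tet2 reads in each of the 11 libraries (points, 1 per library), by group, on a linear axis from 0, with the group mean (bar) and SD (whiskers). Untreated groups overlap, between 1443 and 2382 reads, and the LPS-treated groups lie between 7912 and 16672.

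LPS in control siRNA cells asked how BV2 cells respond to 3 h of LPS with Tet2 at its normal level. A broad inflammatory and interferon programme rose, led in fitted differences by Rsad2, an antiviral enzyme, at 10.03 (SE 0.46), the chemokines Cxcl10 at 9.48 (SE 0.43) and Cxcl2 at 9.10 (SE 0.40), and Irg1, which makes itaconate, at 8.16 (SE 0.32). Fitted differences understate genes with 0 reads untreated, such as Il6, which rose by at least 10.21 log2 units against a floor of 3 counts. Il1b rose by 7.07 (SE 0.26), Nos2, the inducible nitric oxide synthase, by 6.28 (SE 0.48), Tnf by 5.44 (SE 0.33) and Ptgs2, the inducible cyclooxygenase, by 5.07 (SE 0.19). The largest decreases were in Cxcr4, a chemokine receptor, at -3.69 (SE 0.26), Lpin1, a phosphatidate phosphatase, at -3.64 (SE 0.16), Bmf, a pro-apoptotic BCL2 family member, at -3.50 (SE 0.31), and P2ry1, a purinergic receptor, at -3.24 (SE 0.21). In all, 1649 genes rose and 1304 fell of 12486 tested (limma, adjusted p under 0.05), 896 and 478 of them by at least 1 log2 unit.

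Several cytokine genes had 0 reads in all 3 untreated control siRNA libraries, so that their folds are lower bounds against a floor of 3 counts over the group, which covers counting error only. Il6 was at least 1183-fold higher after LPS, with 1097 ± 863 normalised reads (SD, n = 3). Csf3 was at least 126-fold higher, with 117 ± 42.5 normalised reads (SD, n = 3), and Cxcl3 at least 365-fold higher, with 338 ± 144 (SD, n = 3). Ifnb1, the type I interferon gene, was at least 101-fold higher, with 93.4 ± 80.1 (SD, n = 3). Without replicate 2 of the LPS-treated control siRNA cells the bounds were 645-fold for Il6 and 53.6-fold for Ifnb1.

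The fixed gene lists described the LPS response of control siRNA cells as follows, each with its camera test against the other genes. All 20 NF-kB targets and feedback genes rose (median 2.97, adjusted p = 6.81e-27), among them Traf1 by 5.88 and Tnfaip3, a brake on NF-kB signalling, by 4.24. All 39 measured type I interferon-stimulated genes rose (median 5.00, or 5.07 with the member at 0 reads set to its bound, adjusted p = 7.25e-47), among them Mx2 by 7.42. So did 15 of 16 measured cytokines (median 2.58, or 2.83 with bounds, adjusted p = 3.91e-14) and all 14 measured chemokines (median 3.26, or 4.58 with bounds, adjusted p = 1.81e-15), including Ccl5 by 6.45 and Ccl2 by 3.99. Of 18 inducible inflammatory enzymes and effectors, 16 rose (median 2.05, adjusted p = 1.12e-15), while Arg1, which competes with Nos2 for arginine, differed by 0.03 (SE 0.50) and did not pass. Of 26 TLR4 signalling components, 11 rose and 4 fell (median 0.37, adjusted p = 0.00341). Tlr2 rose by 4.36, Irak3, a negative regulator of the pathway, by 1.57 and the LPS co-receptor Cd14 by 1.49. These 6 lists also passed with an estimated correlation between genes, with adjusted p between 0.00503 and 0.0291.

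Another 4 lists passed with the preset correlation only. Antigen presentation genes were higher, with 15 of 17 up (median 1.73, adjusted p = 5.98e-12, and adjusted p = 0.0906 with an estimated correlation), including Cd40 by 5.72, Cd274 by 4.70 and the peptide transporter Tap1 by 3.89. NRF2 targets had 10 of 19 up and 1 down (median 0.78, adjusted p = 7.47e-05, and adjusted p = 0.0906 with an estimated correlation), with Slc7a11, the cystine importer, up by 3.28 and Srxn1 by 2.05. Immediate early genes split, with 11 of 21 up and 3 down (median 1.00, adjusted p = 0.00394, and adjusted p = 0.290 with an estimated correlation). Myc rose by 3.54 and Fos fell by 2.41. Cell cycle genes had a median of -0.35, with 2 of 30 lower, Ccnd1 at -1.66 and Cenpa at -0.67 (adjusted p = 0.0269, and adjusted p = 0.631 with an estimated correlation). The cell cycle call ended without replicate 2 or 3 of the untreated control siRNA cells (medians -0.29 and -0.27) and without replicate 1 or 2 of the LPS-treated ones (-0.33 and -0.34). That of Cenpa ended without replicate 1 of the untreated (-0.57) or replicate 2 of the LPS-treated control siRNA cells (-0.55). Leaving out replicate 3 of the untreated and replicate 1 of the LPS-treated control siRNA cells together ended both gene calls. Ccnd1 was then at -1.14 (limma, adjusted p = 0.0882) and Cenpa at -0.64 (limma, adjusted p = 0.0719).

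The remaining 9 tested lists did not pass with LPS in control siRNA cells, though single members moved. Of 22 homeostatic microglia genes 4 fell and 1 rose (median -0.10, adjusted p = 0.115), with Mertk, a receptor for dying cells, at -1.53 and Mef2c at -1.38. Of 19 DNA methylation and demethylation genes 5 rose and 5 fell, and their median of -0.18 and mean of 0.02 differed in sign (adjusted p = 0.855). Dnmt3l rose by 1.48 and Mbd1 by 1.33, and Cxxc5 fell by 1.92. Of 15 p53 targets 6 rose and 2 fell (adjusted p = 0.0623), with the death receptor Fas up by 3.98, Mdm2 up by 2.34 and Sesn1 at -2.52. Medians lay between -0.30 and 0.23 for disease-associated microglia and lysosome genes (0.11), glycolysis (0.23, adjusted p = 0.117), oxidative phosphorylation (0.12, adjusted p = 0.445), cholesterol synthesis (-0.08, adjusted p = 0.487), the unfolded protein response (-0.16, adjusted p = 0.609) and replication-dependent histones (-0.30, adjusted p = 0.0811).

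LPS in Tet2 siRNA cells asked whether the response was present after transfection against Tet2. The same kinds of gene led it in fitted differences, which understate genes with 0 reads untreated, such as Il6. Cxcl2 rose by 8.59 (SE 0.45), Cxcl10 by 8.42 (SE 0.48), Rsad2 by 7.93 (SE 0.52), Irg1 by 7.42 (SE 0.36), Il1b by 7.13 (SE 0.29), Nos2 by 5.79 (SE 0.53), Tnf by 5.69 (SE 0.37) and Ptgs2 by 5.01 (SE 0.21). The largest decreases included Lpin1 at -3.39 and Cxcr4 at -3.19. Il6 was at least 676-fold higher and Ifnb1 at least 36.0-fold higher, against 0 reads in all 3 untreated Tet2 siRNA libraries and a floor of 3 counts over the group. The bound for Ifnb1 was 16.6-fold without replicate 2 of the LPS-treated Tet2 siRNA cells and 55.4-fold without replicate 3. In all, 891 genes rose and 596 fell (limma, adjusted p under 0.05), 651 and 317 of them by at least 1 log2 unit, from 2 LPS-treated libraries in place of 3.

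Of the genes called in either cell population, 849 rose in both and 547 fell in both, and 0 were called in opposite directions. Independent lists of those sizes would share 118 and 62.2. These comparisons share no library, and their log2 differences correlated across genes, which are not independent replicates, with r = 0.93. By list, all 20 NF-kB targets (median 2.71), 37 of 39 interferon-stimulated genes (median 3.81, or 4.27 with bounds), 12 of 16 cytokines (median 1.93, or 2.61 with bounds), 13 of 14 chemokines (median 3.55, or 4.83 with bounds), 15 of 18 inflammatory enzymes (median 1.98) and 8 of 26 TLR4 components (median 0.30) rose in Tet2 siRNA cells. Those 6 lists passed with both the preset and the estimated correlation, the latter with adjusted p between 0.00202 and 0.0244. Antigen presentation (median 1.28), NRF2 targets (median 0.44), immediate early genes (median 0.89) and p53 targets (median 0.05, mean 0.76, with Fas up by 4.05 and Gdf15 by 3.15) were higher with the preset correlation only. Their adjusted p with an estimated correlation was 0.113, 0.148, 0.228 and 0.0627 in that order. Homeostatic microglia genes were lower (median -0.40, adjusted p = 0.0153, and adjusted p = 0.229 with an estimated correlation). Their call ended without replicate 2 of the LPS-treated Tet2 siRNA cells, where the median was 0.022 (adjusted p = 0.334), and with the stricter filter (-0.16, adjusted p = 0.0614). The other 8 tested lists did not pass.

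**Figure D2:**
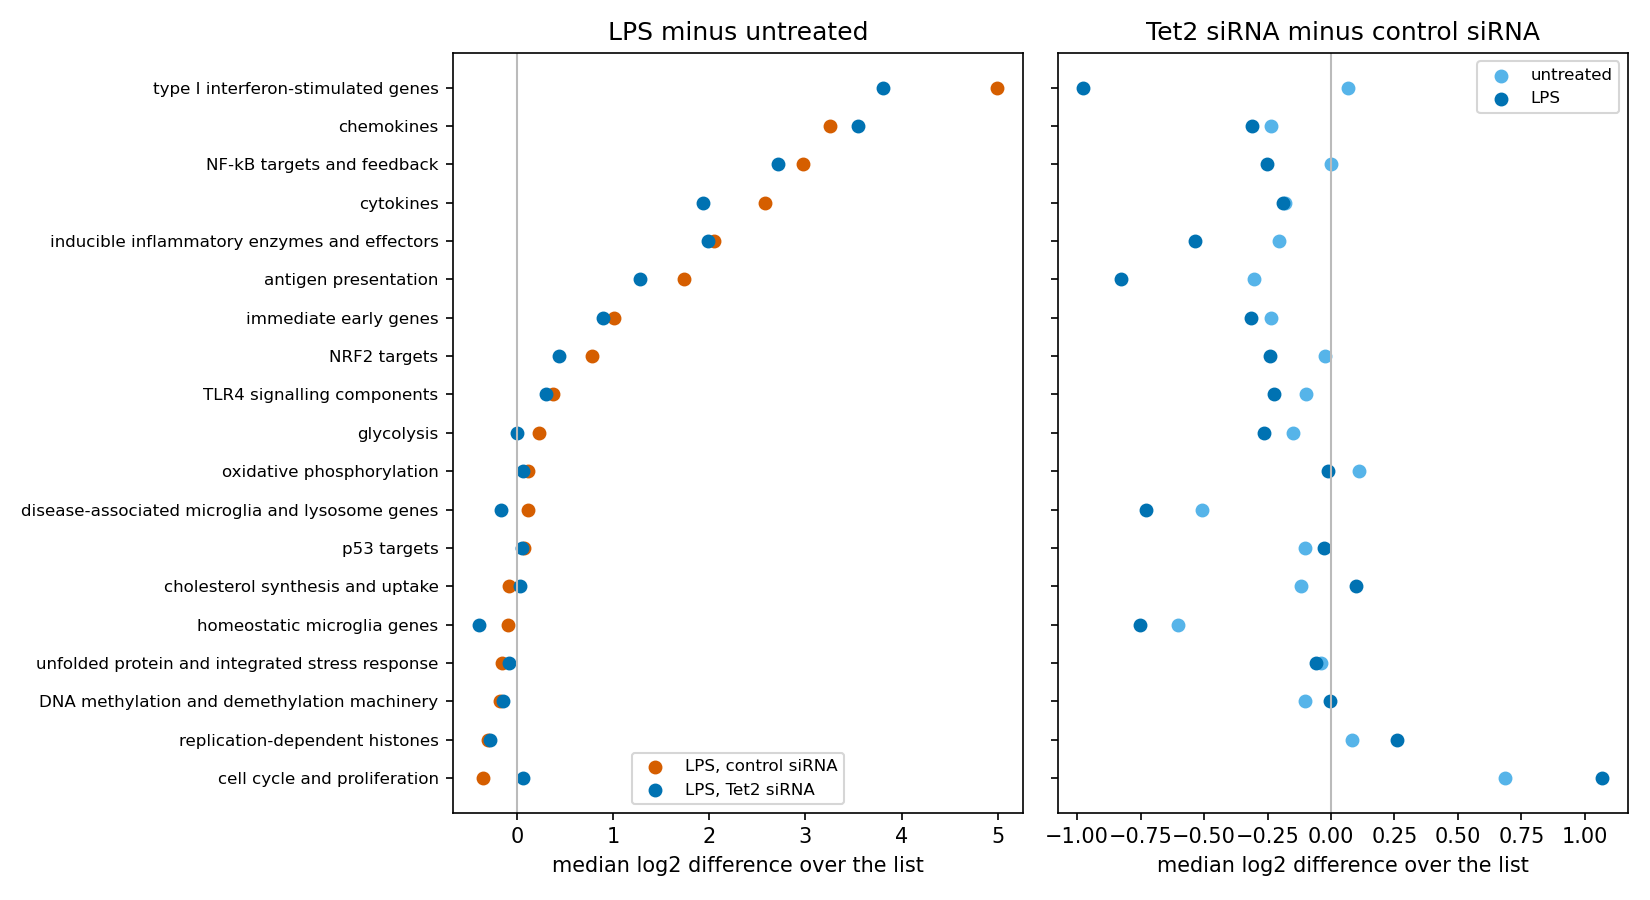
Median log2 difference of each of the 19 tested gene lists: LPS minus untreated in both siRNA groups (left) and Tet2 siRNA minus control siRNA in both treatments (right), 1 point per list and comparison, without error bars. Interferon-stimulated genes lie at 5.00 and 3.81 on the left, and cell cycle genes at 0.69 and 1.07 on the right, where no list passed with an estimated correlation.

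Tet2 siRNA in untreated cells asked what the siRNA changed before LPS, in libraries whose Tet2 levels overlapped. A single gene passed: Klhl30 was lower with Tet2 siRNA, at -1.55 (SE 0.20, adjusted p = 0.0492), 331 normalised reads against 93.7, and 0 genes were higher (limma, 1354 genes at an unadjusted p under 0.05). The next smallest p-values did not pass. They belonged to the complement genes C1qc at -2.15 (SE 0.33, adjusted p = 0.140) and C1qb at -1.85 (SE 0.31, adjusted p = 0.210), Mmp14, a membrane metalloprotease, at -0.89, and Pilrb1 at -1.09. Leaving out any 1 library except replicate 3 of the LPS-treated control siRNA cells left 0 genes called, and voom on recovered reads called 0 genes.

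Among lists in untreated cells, homeostatic microglia genes had a median of -0.60 with Tet2 siRNA (10 of 22 lower when adjusted over the list alone, 0 over all genes), with Aif1 at -1.20 and the receptor Csf1r at -0.75. Disease-associated microglia and lysosome genes had a median of -0.51 (5 of 21 lower over the list alone), with the receptor Axl at -1.57, antigen presentation genes one of -0.30 (1 of 17), and cell cycle genes one of 0.69 (9 of 30 higher), with the mitotic genes Cenpf at 1.14 and Kif11 at 1.01. These 4 lists passed camera with the preset correlation (adjusted p = 1.24e-09, 3.91e-07, 0.00106 and 3.87e-13), and none passed with an estimated correlation (adjusted p = 0.0944, 0.528, 0.528 and 0.528). Of the 10 ways to split these 6 libraries into groups of 3, 7 called at least 4 lists, with up to 8. Without replicate 3 of the untreated control siRNA cells or replicate 2 of the untreated Tet2 siRNA cells, 2 lists were higher in place of 1. The latter library lay farthest from the controls in disease-associated microglia and lysosome genes. Their median deviation from each gene's mean was -0.73 there, and 0.13 and -0.18 in replicates 1 and 3. The untreated control siRNA cells lay at 0.17 to 0.24. Interferon-stimulated genes (median 0.07, adjusted p = 0.470) and NF-kB targets (median 0.00, mean -0.02, adjusted p = 0.993) did not pass before LPS. The other 13 tested lists did not pass either.

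Tet2 siRNA in LPS-treated cells is the comparison closest to the series' subject, Tet2 in the inflammatory response of microglia. No gene passed in 2 libraries against 3 (limma, 0 higher and 0 lower, smallest adjusted p = 0.0833, 2131 genes at an unadjusted p under 0.05, and 0 calls with voom on recovered reads). The smallest p-values belonged to Scel at -1.34 (SE 0.20), Mmp14 at -1.26 (SE 0.19), the transcription factor Maf at -1.38 (SE 0.21), Axl at -2.39 (SE 0.38) and the co-stimulatory gene Cd86 at -1.07 (SE 0.18). Of the inflammatory genes, Tnf at -0.07 (SE 0.37) and Il1b at -0.18 (SE 0.29) differed by less than their error. Nos2 at -1.10 (SE 0.53, adjusted p = 0.317), Cxcl10 at -0.96 (SE 0.48, adjusted p = 0.322) and Ifnb1 at -0.82 (SE 0.45, adjusted p = 0.372) differed by more than theirs and did not pass. Single libraries moved these 3: Nos2 was at -0.39 without replicate 2 of the LPS-treated Tet2 siRNA cells and -1.81 without replicate 3, and Cxcl10 at -0.63 without replicate 2 of the LPS-treated control siRNA cells. Ifnb1 was at -0.31 without that library and -1.35 without replicate 3 of the same group, and at -1.31 and -0.34 without replicates 2 and 3 of the LPS-treated Tet2 siRNA cells. Arg1 was at -2.23 (SE 0.56, adjusted p = 0.122), and its libraries lay apart too. It held 252 and 1126 normalised reads in replicates 2 and 3 of the LPS-treated Tet2 siRNA cells. The LPS-treated control siRNA cells held 2250 to 3038. Leaving out replicate 3 of the LPS-treated control siRNA cells gave 19 genes higher and 101 lower.

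By list in LPS-treated cells, interferon-stimulated genes had a median of -0.98 with Tet2 siRNA and all 39 lay below 0 (29 lower over the list alone), with the antiviral GTPases Igtp at -1.48 and Mx2 at -1.32 and Oasl1 at -1.08. Antigen presentation genes had a median of -0.83 (12 of 17 over the list alone), with Tap1 at -1.51. Homeostatic microglia genes lay at -0.75 (11 of 22), with C1qa at -1.88, C1qb at -1.76 and Aif1 at -1.56, and disease-associated microglia and lysosome genes at -0.73 (11 of 21). The median deviation of the latter list from each gene's mean was -0.74 and -0.11 in replicates 2 and 3 of the LPS-treated Tet2 siRNA cells. It was 0.15 to 0.45 in the LPS-treated control siRNA cells. For antigen presentation genes these values were 0.087 and 0.62, against 0.65 to 1.56. Cell cycle genes lay at 1.07 (23 of 30 higher over the list alone), with Ccna2 at 1.46, Kif11 at 1.35 and Cenpf at 1.30. Inflammatory enzymes (-0.53, 3 of 18 lower over the list alone), immediate early genes (-0.31, 0 of 21), glycolysis (-0.26, 2 of 21) and NF-kB targets (-0.25, 0 of 20) were lower too with the preset correlation, though not with an estimated one (adjusted p = 0.252, 0.403, 0.338 and 0.338). With the preset correlation 8 lists were lower and 1 higher, with adjusted p from 2.31e-18 to 0.0296. None of the 9 passed with an estimated correlation, where adjusted p ran from 0.186 for homeostatic microglia genes to 0.403 for immediate early genes. The calls of inflammatory enzymes (-0.25), immediate early genes (-0.31) and NF-kB targets (-0.16) ended without replicate 2 of the LPS-treated Tet2 siRNA cells. When replicate 2 of the LPS-treated control siRNA cells was left out, those of immediate early genes (-0.29) and NF-kB targets (-0.27) ended, and without replicate 1 those of glycolysis (-0.12) and NF-kB targets (-0.19). Quantile normalisation also ended the calls of glycolysis (-0.12, adjusted p = 0.206) and NF-kB targets (-0.18, adjusted p = 0.212), and library weights that of NF-kB targets (-0.20, adjusted p = 0.0586). The other 10 tested lists did not pass.

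**Figure D3:**
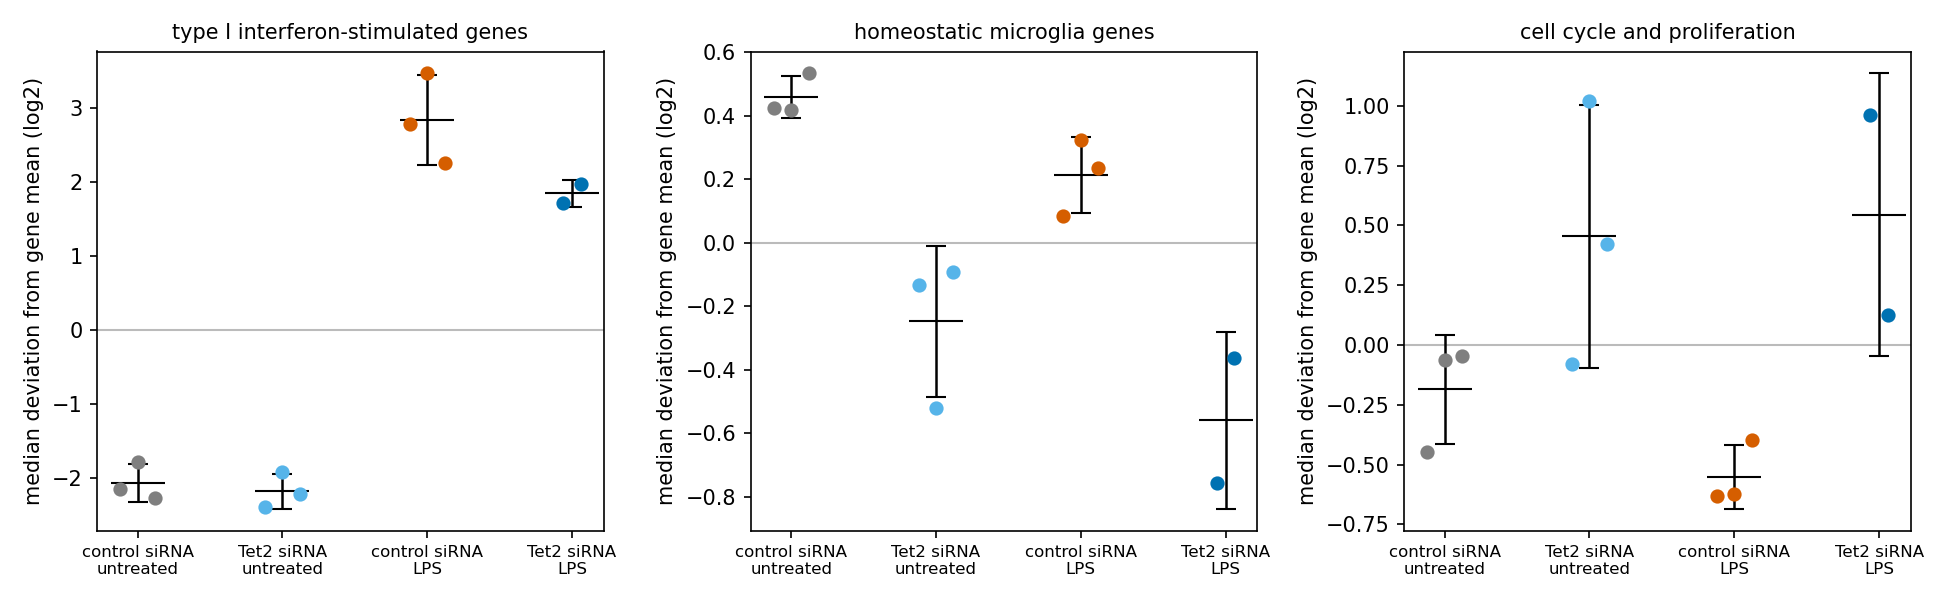
Median deviation of 3 gene lists from each gene's mean over all libraries (log2), 1 point per library, with the group mean (bar) and SD (whiskers). Homeostatic microglia genes lie between -0.76 and -0.09 in the 5 Tet2 siRNA libraries and between 0.09 and 0.53 in the 6 control siRNA libraries, while cell cycle genes overlap between the untreated groups. Replicate 2 of both Tet2 siRNA groups lies farthest from the control siRNA cells in cell cycle genes (1.02 and 0.96) and in homeostatic microglia genes (-0.52 and -0.76).

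The difference between both LPS responses asked whether Tet2 siRNA changed the response itself. No single gene passed (limma, 0 higher and 0 lower, smallest adjusted p = 1.00, 281 genes at an unadjusted p under 0.05, and 0 calls with voom on recovered reads). As a set, the LPS-responsive genes responded less in Tet2 siRNA cells. Over 1994 genes induced by LPS on average of both siRNA groups, the median difference in response was -0.24, and 1586 of them lay below 0, beside a median average response of 0.80. Over 1780 repressed genes it was 0.15, beside a median average response of -0.67. Both sets passed camera with the preset correlation (adjusted p = 1.02e-22 and 1.45e-10) and with an estimated one (adjusted p = 0.0125 and 0.00825). Without replicate 2 of the LPS-treated Tet2 siRNA cells the induced median was -0.12 and the repressed median 0.078. The choice of these genes is independent of the difference only if all libraries vary alike. Estimated library weights were lowest in control siRNA cells, in replicate 3 of the untreated and replicate 1 of the LPS-treated ones. They were 0.17 and 0.24, or 0.20 and 0.28 gene by gene. A bias of the choice towards a smaller response is therefore not excluded.

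Among single genes the difference in response was -2.05 (SE 0.56) for Ifit2, -1.84 (SE 0.52) for Ifit3, -1.57 (SE 0.41) for Mx2 and -1.49 (SE 0.44) for Igtp, all interferon-stimulated, and none passed. Outside the lists the smallest p-values were those of Tapbpl at -1.15, Rufy4 at -1.27 and Rin2 at -1.02. Tnf, at 0.25 (SE 0.50), and Il1b, at 0.06 (SE 0.39), differed by less than their error. Of the 39 interferon-stimulated genes 38 had a smaller response with Tet2 siRNA (median -1.03, 4 lower over the list alone, adjusted p = 1.43e-29 with the preset correlation and adjusted p = 0.453 with an estimated correlation). Antigen presentation genes had a median of -0.55, NRF2 targets of -0.26, disease-associated microglia and lysosome genes of -0.24, NF-kB targets of -0.22 and glycolysis genes of -0.10, and cell cycle genes one of 0.37. Those 6 lists too passed with the preset correlation only, with adjusted p between 0.541 and 0.772 with an estimated one. Without replicate 2 of the LPS-treated Tet2 siRNA cells the calls of 5 lists ended, with antigen presentation at -0.20, NF-kB targets at -0.061, glycolysis at -0.056, disease-associated microglia and lysosome genes at 0.033 and cell cycle genes at 0.031. The cell cycle call also ended without replicate 1 of the untreated Tet2 siRNA cells (0.12), and that of NRF2 targets without that library (-0.19) or replicate 1 of the LPS-treated control siRNA cells (-0.19). Of 11 libraries left out in turn, 4 ended the call of NF-kB targets, 7 that of glycolysis genes, 7 that of disease-associated microglia and lysosome genes, and 0 that of interferon-stimulated genes. The calls of NF-kB and NRF2 targets ended with quantile normalisation (medians -0.051 and -0.090) and with library weights (-0.040 and -0.057). That of disease-associated microglia and lysosome genes ended with quantile normalisation (-0.015) and the replicate block (-0.15), and that of glycolysis genes with the stricter filter, quantile normalisation (0.081), median centring, no variance trend and the replicate block. The other 12 tested lists did not pass.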

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

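All tests of reads found in a single library and of the interferon-stimulated genes were chosen only after the result was seen. So were, as tests of the siRNA pattern, those of a state of the cultures and of libraries left out. Leaving out each library in turn was itself fixed before the data were examined. The removal of length and GC trends was chosen after the data had been seen. Only what its outcome would mean was fixed before that outcome was seen.

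Replicate 3 of the untreated control siRNA cells held reads on 2025 genes that had 0 reads in the other 10 libraries, 5841 reads in all, against 5 to 206 such genes in each other library. Greater depth is argued against, since the library held 8.76 M reads beside a median of 18.8 M. RNA of another cell type is argued against, since the 10 strongest of these genes held only 3.29% of their reads, and abundant foreign transcripts would concentrate them. Genomic DNA in the library may account for it: reads rose with transcript length (Spearman rho = 0.273 across genes, at most 0.0637 in the other libraries). Detection rose from 8.58% of the shortest transcripts to 37.1% of the longest, split in 4 by length. Few such genes had reads in the other libraries, so ties at 0 hold their rho low. Reads of RNA at a low level can rise with length too, so the relation does not tell DNA from RNA. Satellite-like genes held 8213 CPM in this library and 26.6 to 480 elsewhere.

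The LPS response differed between siRNA groups, by the test of the difference itself, for genes induced by LPS (-0.24) and for genes repressed by it (0.15), and both held with an estimated correlation. With the preset correlation alone it also differed for interferon-stimulated genes (-1.03), antigen presentation (-0.55), NRF2 targets (-0.26), disease-associated microglia and lysosome genes (-0.24), NF-kB targets (-0.22), glycolysis (-0.10) and the cell cycle (0.37), of which none held with an estimated correlation. Without replicate 2 of the LPS-treated Tet2 siRNA cells, interferon-stimulated genes and NRF2 targets were the only 2 of these 7 lists still called.

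For the interferon-stimulated genes, of which Rsad2, Ifit2 and Mx2 are members, replicate 2 of the LPS-treated Tet2 siRNA cells as the whole cause is argued against, since the median difference in response was -0.82 without it. That leaves a group of 1 library, assumed to vary like the others. Over all libraries left out in turn this median ran from -1.27 to -0.69. Median deviations of the list from each gene's mean were 1.72 and 1.97 in replicates 2 and 3 of the LPS-treated Tet2 siRNA cells. In replicates 1, 2 and 3 of the LPS-treated control siRNA cells they were 2.78, 3.47 and 2.26. The difference thus depends on replicate 2 of those controls more than on which Tet2 siRNA library is kept. A grouping by chance stays open: 2 of the 10 splits of the 5 LPS-treated libraries gave a median as large as the real -0.98, the other reaching 1.08, and splits this few cannot give a share under 0.05. A weaker response to LPS as a whole cannot be told apart from one of interferon genes, since NF-kB targets kept a median share of 0.933 of their response, cytokines 0.951, chemokines 1.02, inflammatory enzymes 0.927, immediate early genes 0.849, TLR4 components 0.810, interferon-stimulated genes 0.794, antigen presentation 0.759 and NRF2 targets 0.651, with no test of those shares. Lower Tet2, the difference the design names, may also account for it and stays untested, since the design does not separate Tet2 from other effects of the siRNA. Tet2 itself differed by only -0.67 after LPS.

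Across both treatments cell cycle genes were higher with Tet2 siRNA (median 0.90 on average of treatments) and homeostatic microglia genes lower (-0.65), a comparison chosen after the data were seen, in which neither list passed with an estimated correlation (adjusted p = 0.307 and 0.108). Transcript length or GC trends as the whole cause are argued against, since the cell cycle median was 0.86 and the microglia median -0.64 after their removal; without replicate 3 of the untreated control siRNA cells the cell cycle median was 0.91 and without replicate 2 of the LPS-treated Tet2 siRNA cells 0.74, which argues against either alone as the whole cause of the cell cycle median, though genes called one by one went from 540 to 48 and 0. Replicate 2 of both Tet2 siRNA groups stood apart together, in cell cycle genes at 1.02 untreated and 0.96 after LPS, against -0.080, 0.42 and 0.13 in the other 3 Tet2 siRNA libraries; without both, the medians were 0.52 and -0.49, with 0 genes called. A state of the cultures that varies between replicates, such as density, stays open: within groups, cell cycle and microglia medians ran opposite (Pearson r = -0.73, permutation p = 0.255, Spearman rho = -0.63, permutation p = 0.262, r = -0.57 without the 2 farthest of 11 libraries). That this p should pass was required only after r was seen, and on r alone the relation would have counted for a state of the cultures, so it cannot be told apart from an effect of the siRNA. Replicate 2 of the untreated Tet2 siRNA cells held 1974 normalised Tet2 reads, level with replicate 1 of the untreated control siRNA cells. Among LPS-treated Tet2 siRNA cells, replicate 2 held 7912 and replicate 3 held 9172.

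Other splits of the libraries bear on the counts of calls. LPS in control siRNA cells called 2953 genes and 10 lists, the highest of the other splits 0 genes and 9 lists, each real value being reached by 1 of 10 splits. Tet2 siRNA in untreated cells called 1 gene, reached by 1 of 10 splits (highest other 0), and 4 lists, reached by 7 of 10 splits (highest other 8). With 10 splits the share cannot fall under 0.05.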

How the results depend on the processing

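The alternatives chosen only after the result was seen were voom on recovered reads, removal of length and GC trends, leaving out replicate 3 of the untreated and replicate 1 of the LPS-treated control siRNA cells together, leaving out replicate 2 of both Tet2 siRNA groups together, the gene-by-gene library weights, and everything on the effect pooled over treatments.

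LPS in control siRNA cells gave 1332 to 2133 genes higher and 992 to 1896 lower under all alternatives but leave-one-out, and Tet2 rose with LPS under every one. The smaller LPS response with Tet2 siRNA also kept its direction. Its induced median ran from -0.26 to -0.13 and its repressed median from 0.094 to 0.16. Its call was kept with the preset correlation, while the estimated correlation was applied to the main fit only. Keeping that call says little, since the preset correlation called at least 4 lists in 7 of 10 splits of the untreated libraries. With libraries left out or weighted, the fixed weights of both LPS effects do not make the choice of genes independent of the difference. In the main fit they do so only if all libraries vary alike. Quantile normalisation moved the median of all genes for LPS in control siRNA cells to -0.088, and its split of 1332 higher to 1467 lower stands beside 1649 to 1304. Without the filter that median was -0.10.

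The cause was not tested for any change below unless named. The estimate of library weights stopped before convergence, with a weight of 44.3 for replicate 3 of the untreated Tet2 siRNA cells. For Tet2 siRNA untreated these weights gave 414 genes higher and 729 lower, after LPS 2 and 11, pooled over treatments 899 and 1331, and for LPS in Tet2 siRNA cells 1657 and 1415. The gene-by-gene estimator, with a largest weight of 9.57, gave 83 and 215 untreated, 4 lower after LPS, 703 and 1036 pooled, and 1487 and 1245 for LPS in Tet2 siRNA cells. The untreated Tet2 difference then passed an unadjusted p of 0.05, at -0.42 with library weights, -0.41 gene by gene, -0.40 with length and GC trends removed and -0.37 with both control libraries left out.

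The single gene lower with Tet2 siRNA untreated became 0 with no filter, quantile normalisation, only the groups compared (fewer samples), voom, length and GC trends removed, and both control libraries left out. After LPS, 1 gene was lower with length and GC trends removed and 1 with both control libraries left out. With those left out, LPS in Tet2 siRNA cells lowered 933 genes, and the pooled effect gave 0 higher and 13 lower. With replicate 2 of both Tet2 siRNA groups left out, which leaves 1 LPS-treated Tet2 siRNA library, Tet2 siRNA untreated gave 0 genes lower, LPS in Tet2 siRNA cells 262 lower and the pooled effect 0 higher and 0 lower. The Tet2 difference after LPS was then -0.57, and its unadjusted p was no longer under 0.05. The same setting gave 2 lists lower for LPS in control siRNA cells, 2 lists higher and 5 lower for Tet2 siRNA untreated, and 3 lists lower for the difference in response. The pooled effect with no filter (more genes tested) gave 129 and 151.

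Lists called moved too. With an estimated correlation, LPS in control siRNA cells had 0 lists lower, LPS in Tet2 siRNA cells 6 higher and 0 lower, and Tet2 siRNA untreated, Tet2 siRNA after LPS and the difference in response each 0 higher and 0 lower. For LPS in control siRNA cells, lists lower were 2 with only the groups compared, and 0 with either library weights and with both control libraries left out. For Tet2 siRNA untreated, length and GC trends removed gave 2 lists higher and 5 lower, and either library weights 6 lower. For Tet2 siRNA after LPS, 2 lists were higher with no filter and with only the groups compared. For LPS in Tet2 siRNA cells, 0 lists were lower with the stricter filter and 2 with quantile normalisation. For the difference in response, lists higher were 2 with the stricter filter, quantile normalisation, voom and length and GC trends removed, and 3 with either library weights, and lists lower were 2 with quantile normalisation, where the glycolysis median reversed to 0.081. The difference in response and its size could not be had from only the groups compared, which need all 4 groups.

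Replicate numbers were shared by groups, but not taken as pairing: 8 of 15 same-numbered pairs of libraries deviated together with r over 0.1, with r from -0.28 to 0.63, and 8 of 30 pairs of other numbers. The 6 pairs of replicates 2 had r from 0.012 to 0.63. These counts include pairs with the 2 LPS-treated Tet2 siRNA libraries, whose r mirror each other because a group of 2 deviates in opposite directions. The replicate block gave 2 lists higher for Tet2 siRNA after LPS, and under the block Klhl30 no longer passed untreated (adjusted p = 0.0916) while C1qc did (adjusted p = 0.0359). In the difference in response it also ended the calls of disease-associated microglia and lysosome genes (adjusted p = 0.142) and glycolysis (adjusted p = 0.104), and in the pooled effect that of Ube2c (adjusted p = 0.0572) while a second list was higher. It changed no other call of a named gene or list and moved no count of genes by over 1.5 times.

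Leaving out each library in turn, where an arm of 1 library is assumed to vary like the others, gave these ranges. LPS in control siRNA cells: 1281 to 1638 genes higher, 954 to 1318 lower, 9 to 10 lists higher, 0 to 1 lower, Tet2 2.57 to 2.92. LPS in Tet2 siRNA cells: 504 to 1038 higher, 288 to 736 lower, 10 to 11 lists higher, 1 to 3 lower, Tet2 2.22 to 2.44. Tet2 siRNA untreated: 0 higher, 0 to 1 lower, 1 to 2 lists higher, 3 to 4 lower, Tet2 -0.40 to -0.17. Tet2 siRNA after LPS: 0 to 19 higher, 0 to 101 lower, 1 to 2 lists higher, 5 to 9 lower, Tet2 -0.87 to -0.53, with the unadjusted p of Tet2 no longer under 0.05 without replicate 2 of the LPS-treated Tet2 siRNA cells. Difference in response: 0 higher, 0 lower, 0 to 2 lists higher, 2 to 7 lower, induced median -0.37 to -0.12, repressed 0.078 to 0.20. Pooled effect: 0 to 460 higher, 0 to 522 lower. Without replicate 2 of the LPS-treated Tet2 siRNA cells the list test of the difference in response turned its direction, without passing, for disease-associated microglia and lysosome genes and for cell cycle genes. Their medians ran from -0.55 to 0.033 and from 0.031 to 0.81 over the libraries left out, so that the cell cycle median fell to near 0 and kept its sign.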

Other observations

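The comparison pooled over treatments was chosen only after the result was seen, in both of its forms; its count over splits was fixed before that count was seen.

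Averaged over treatments with weights of 5/9 and 4/9, Tet2 siRNA cells had 252 genes higher and 288 lower (limma, adjusted p under 0.05). All had the same sign untreated and after LPS, which choosing genes by the average of these same differences largely sets in advance. The other pooled form tried, an additive model of LPS and siRNA, gave 344 and 408. The lower genes included the complement gene C1qc at -2.03 (SE 0.25, adjusted p = 0.00809), the decoy receptor Il1r2 at -2.02 and Arg1 at -1.98. Others were the mannose receptor Mrc1 at -1.93, the receptor Axl at -1.93 and F13a1 at -1.88. The complement genes C1qb at -1.81 and C1qa at -1.70, Aif1 at -1.36 and Cd74 at -1.23 were lower too. The higher genes were led by Lmnb1, a nuclear lamin, at 1.64, and the mitotic genes Kif15 at 1.55, Ube2c at 1.51, Cenpf at 1.21 and Kif11 at 1.16. Of the fixed lists, 13 of 30 cell cycle genes were higher, and 8 of 22 homeostatic microglia genes, 5 of 21 disease-associated microglia and lysosome genes and 3 of 17 antigen presentation genes were lower. None of those lists passed with an estimated correlation (adjusted p = 0.307, 0.108, 0.307 and 0.307 in that order). Tet2 itself was at -0.46 (adjusted p = 0.0890).

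Whether these genes pass depends on single libraries. Leaving out 1 library gave between 0 and 933 calls: 0 without replicate 2 of the LPS-treated Tet2 siRNA cells, 16 without replicate 2 and 29 without replicate 3 of the untreated Tet2 siRNA cells, 20 without replicate 2 of the LPS-treated control siRNA cells, and 48 without replicate 3 of the untreated control siRNA cells. The differences themselves moved less: where 0 genes were called, C1qc lay at -1.87 (adjusted p = 0.0570), Mrc1 at -1.87, C1qa at -1.74, Aif1 at -1.34 and Kif11 at 1.05, and Arg1 at -1.53. Of 100 splits within treatments, the real one included, 1 gave as many calls as the real 540, and the highest other gave 2. The comparison was chosen after the data were seen, so this share does not exclude a grouping by chance. The splits also take libraries as exchangeable, while replicates 2 of the untreated and LPS-treated Tet2 siRNA cells deviated together (r = 0.63). In a group of 2 libraries the deviations mirror each other, so replicate 3 of the LPS-treated cells has r = -0.63. This r does not tell which of them stood apart. Nor do the splits exclude a state shared by the cultures of one siRNA. LPS averaged over both siRNA groups called 3774 genes, reached by 1 of 100 splits, the highest other being 2614.

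Mitochondrially encoded RNAs had 0 reads counted in all libraries. The gene annotation is not given, so whether these genes were counted at all cannot be told. The 0 therefore does not show that their RNA was absent.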
